A study of Arabidopsis thaliana with 20 samples.

How the data were processed

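Whole seedlings of Arabidopsis thaliana, ecotype Columbia, were measured in 20 groups on single-colour millichips. Per the labels, seedlings grew hydroponically for 10 days, total RNA was amplified and labelled with Cy3, and each chip had 4489 spots. Light levels were 80 and 400 in a unit that the labels give only in part, heat was a chamber at 37 °C, cold was ice in a chamber at 10 °C, salt was 200 mM NaCl in 10 mL of medium, and dehydration was 5 h on damp filter paper. The ABA dose is truncated in the labels and is not given here.

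The deposited chip files give, per the file headers, the mean brightness of each spot as an intensity, with background included. The authors' deposited value table gives 1 intensity per probe and group, on a linear scale, and the steps behind it are not stated. Image software and its settings are not given in the sources used here. The files mark 3333 blank spots, 911 gene probes and 245 control spots. The labels instead give blanks as 1 in 4 of the spots. This conflict is not resolved, and every value that uses blank spots rests on the marks in the files.

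Each of the 448 chip files was assigned to its group and replicate by its name, as the labels describe. Of these, 6 were left out because at least 1% of their spots were missing. Another 11 were left out because the same scan stood under 2 labels (5 as ABA and 6 as ABA control; scans were called the same when at least 5% of spot values were equal, against at most 0.757% in other pairs). The remaining 431 chips came from 115 biological replicates, with 1 to 8 chips each. In 3 files the replicate number in the title line differed from that in the file name, and the file name was used. Replicate numbers were tested for pairing and did not pair across groups (mean correlation 0.00811), so no pairing was used.

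Intensities were background-corrected with limma's normexp method (offset 50) and put on a log2 scale. Spots were averaged to probes and probes to 927 genes, including 16 actin-related loci on control spots, and chips were quantile normalised. Chips of a biological replicate were averaged. Genes were tested when they exceeded the 95th percentile of the blank spots on at least 50% of the chips of at least 1 group, which kept 798 and left out 129. The number of arrays limits the precision, and the median SE of a comparison with control was 0.178.

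A group-means model over the 20 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 95 residual degrees of freedom). Each stress was compared with control, each stress was averaged over the backgrounds of the factorial, pairs were tested against the sum of their parts, and terms of light, temperature and water together were tested with a joint F test. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and genes with adjusted p under 0.05 were called. Genes above the blank spots on no chip of a group are given as lower bounds. Figures were drawn with python 3.11.15 and matplotlib 3.10.9. No genome build was used.

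The comparisons, the rule for named genes, 16 gene lists and most alternatives were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall among those called for each single stress and ABA, the 5 largest each way for combinations, averages and interactions, and any measured member of a list. The lists were written from general knowledge, without reference to these chips: ABA and dehydration response; ABA receptors, phosphatases and kinases; ABA synthesis and breakdown; heat shock proteins and factors; cold response; proline, galactinol and starch metabolism; flavonoid and anthocyanin synthesis; reactive oxygen scavenging; photosynthesis; ion and proton transport; aquaporins; circadian clock; jasmonate, wounding and defence; root-enriched genes; seed storage; and usual reference genes. The 9 lists with at least 3 measured genes were tested with limma's camera (preset correlation 0.01) in 20 comparisons, and p-values were adjusted over the 180 pairs. Of these, 60 had an unadjusted p under 0.05, 40 were called, and 30 of the 40 were also called with an estimated correlation. Regrouped samples gave a median of 17 calls with the preset correlation and 0 with the estimated one. Calls with the preset correlation alone are therefore weak. The ABA and dehydration response and cold-response lists share 3 genes (ERD10, RD29A and LEA14), so their tests are not independent. The root-enriched and seed storage lists had no measured gene.

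Alternatives were median scaling, no background correction, background from the blank spots, no filter on dim genes, the median over probes, a block for file format, a block for replicate number, leaving out chips whose Spearman correlation with the rest of their group was under 0.8, keeping chips separate with replicate as a random block, fitting only the groups compared, an estimated correlation in camera, the authors' table, and leaving out replicates in turn for heat + dehydration and for high light + heat + salt. Chosen after seeing the data were: files with 9 columns only, leaving out the chips labelled ABA and ABA control, all chips as labelled, ABA replicates numbered by the title line, the authors' table for the correlations, and leaving out replicates in turn in all other comparisons, those of the chips labelled ABA and ABA control included. The method was tested on simulated data with 200 changed genes: for heat against control 32% were called at 1.25-fold, 78% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 3.15% of calls were unchanged genes. For heat + salt off the sum 10% were called at 1.25-fold, 50% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. For the joint term of light, temperature and water these were 8%, 16%, 68% and 100%. The simulated noise was independent between genes and took its spread from the groups of the factorial alone. The real fit also held the chips labelled ABA and ABA control, so these shares need not hold for it.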

Results

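Whole seedlings of Arabidopsis thaliana, ecotype Columbia, were grown for 10 days in liquid culture and then given heat, cold, salt, dehydration or high light, alone and in combination, or abscisic acid (ABA), the hormone of the water-deficit response. Transcripts were measured on millichips, small single-colour arrays whose Cy3 intensity reports the amount of labelled RNA bound to each probe. The stresses formed a factorial of 18 groups in which 2 light levels, 3 temperatures and 3 water conditions were crossed, and chips labelled ABA and ABA control made 2 further groups. From 448 chips, 431 were used, and these came from 115 biological replicates. Groups had 6 biological replicates except heat + dehydration, ABA and ABA control with 5 each and high light + heat + salt with 4. The number of chips per group ran from 10 for ABA control to 36 for cold + salt and limited the precision. The median share of genes whose signal lay above the blank spots was 69.4% on control chips and ran from 57.8% to 76.4% over the other groups of the factorial, but was 32.6% on the chips labelled ABA control. Of 927 genes on the chip, 798 were bright enough to be tested. All changes below are log2 differences ± SE from limma, unless a fold is named, and each stress was compared with untreated seedlings of 6 replicates.

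The comparison of heat with control asked which genes respond to a chamber at 37 °C. Chaperone genes rose: HSP101 (AT1G74310), which dissolves protein aggregates, rose 38.0-fold (5.25 ± 0.17, n = 6), the small heat shock protein gene AT2G29500 rose 52.5-fold (5.71 ± 0.20) and HSP70 (AT3G12580) rose by 3.80 ± 0.18. AT1G21945 and AT1G58140 rose further, by 6.13 ± 0.19 and 5.89 ± 0.19. The galactinol synthase gene GOLS1 rose by 4.60 ± 0.23, while ENODL2 (-2.42 ± 0.20), the beta-amylase gene BMY3 (-2.25 ± 0.17) and AT5G57760 (-2.21 ± 0.19) fell. AT5G05250 fell at least 1.47-fold, since it was not above the blank spots in heat. Each of these genes moved the same way in 6 of 6 heat replicates. Of the 7 measured heat shock proteins and factors, 6 rose and none fell, also adjusted over the list alone (median 2.17, adjusted p = 8.03e-09). HSFA1B, at -0.03 ± 0.15, was the member that did not pass. Cold-response genes went both ways, with 4 of 8 rising (5 adjusted over the list alone), among them KIN1 (1.90 ± 0.23) and COR47 (1.67 ± 0.15), and 2 falling, COR413-PM1 (-1.73 ± 0.15) and COR15A (-1.51 ± 0.29). In the ABA receptor, phosphatase and kinase list 4 of 21 rose and 8 fell, among them PYL7 (0.95 ± 0.16), which rose, and PYR1 (-1.03 ± 0.17) and ABF2 (-1.07 ± 0.19), which fell. The list of ABA and dehydration response genes was not called as a set (adjusted p = 0.493), with 4 of 22 rising and 2 falling, also adjusted over the list alone. All 4 usual reference genes fell, also adjusted over the list alone, but the list was not called (adjusted p = 0.0625). It was called without background correction (adjusted p = 0.0309), with background from the blank spots (0.0482), without the filter on dim genes (0.0403), without chips of low correlation (0.0351) and without the chips labelled ABA and ABA control (0.0477). In all, 424 genes changed, of which 186 rose and 238 fell. With median scaling the split was 235 and 196.

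The comparison of cold with control asked which genes respond to ice in a chamber at 10 °C. The ubiquitin ligase gene PUB19 rose at least 6.56-fold, being above the blank spots on no control chip. The heat shock factor gene HSFA6B rose 8.42-fold (3.07 ± 0.28, n = 6), AT3G60930 7.81-fold (2.97 ± 0.15), SEN1 by 2.81 ± 0.22, the copper protein gene BCB 5.66-fold (2.50 ± 0.20) and JAZ1, a repressor of jasmonate signalling, 4.71-fold (2.23 ± 0.22). AT5G57760 (-1.81 ± 0.19), the ascorbate peroxidase gene APX1 (-1.56 ± 0.24) and the ABA receptor genes PYL4 (-1.23 ± 0.15) and PYL1 (-1.18 ± 0.18) fell, each in 6 of 6 replicates. Of 8 cold-response genes, 4 rose and none fell (5 and 1 adjusted over the list alone): ERD10 (1.97 ± 0.18), RD29A (1.32 ± 0.24), COR47 (1.02 ± 0.15) and LEA14 (0.78 ± 0.18), while COR15A was at 0.03 ± 0.29. That list was called with the preset correlation (adjusted p = 0.00484), but adjusted p = 0.136 with an estimated correlation. Among 3 circadian clock genes, PRR9 (1.38 ± 0.19) and RVE1 (1.06 ± 0.16) rose and none fell, also adjusted over the list alone, and the list was called (adjusted p = 0.0280, and adjusted p = 0.0488 with an estimated correlation). That call ended without background correction (adjusted p = 0.0644), with background from the blank spots (0.0541) and with chips kept separate (0.0669). Of the 22 ABA and dehydration response genes 5 rose and 1 fell (8 and 2 adjusted over the list alone). In all, 185 genes changed, 82 up and 103 down, and median scaling gave 89 and 65. The count was 295 when the spread was estimated from these groups alone.

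Salt, 200 mM NaCl in the medium, was compared with control for the same purpose. Many ABA-inducible genes rose: RD20 (AT2G33380), a caleosin, rose 31.3-fold (4.97 ± 0.22, n = 6), TSPO (AT2G47770) 24.9-fold (4.64 ± 0.22), and the late embryogenesis abundant genes LEA7 16.4-fold (4.04 ± 0.18) and LEA4-5 by 3.81 ± 0.20. P5CS1, the enzyme of proline synthesis, rose 9.92-fold (3.31 ± 0.21) and ORA47 rose at least 5.29-fold. Of 22 ABA and dehydration response genes 18 rose and none fell, also adjusted over the list alone, with a median of 1.42 (adjusted p = 7.23e-14). Some ABA receptor genes fell: PYL4 by 10.1-fold (-3.34 ± 0.15), PYR1 3.60-fold (-1.85 ± 0.17), PYL6 3.46-fold (-1.79 ± 0.21) and PYL5 3.41-fold (-1.77 ± 0.17). In the list that holds them, 7 of 21 rose (8 adjusted over the list alone), among them the phosphatase gene ABI1 (1.26 ± 0.20) and PYL7 (1.13 ± 0.16), and 8 fell. That list had a median of 0.09 and a mean of -0.28, and was not called (adjusted p = 0.628). All 8 cold-response genes rose, also adjusted over the list alone (adjusted p = 1.46e-06), with COR15A at 2.42 ± 0.29. All 5 proline, galactinol and starch genes rose as well (adjusted p = 0.000332), also adjusted over the list alone. The 4 usual reference genes fell, also adjusted over the list alone, with ACT2 at -1.11 ± 0.10 (adjusted p = 0.0337, adjusted p = 0.159 with an estimated correlation, and 0.0563 with median scaling). Their mean lay below control in every single and combined stress, from -0.21 in high light to -1.01 in high light + dehydration. The fall is therefore not particular to salt, and its cause was not tested. Genes of lists too small to test included the aquaporin gene PIP2;1 (2.14-fold), the sodium antiporter gene NHX2 (0.75 ± 0.23) and JAZ1 (1.53 ± 0.22), which rose, and the light-harvesting gene LHCB6 (-0.99 ± 0.18) and ABA2 of ABA synthesis (-0.47 ± 0.17), which fell. In all, 376 genes changed, 156 up and 220 down. ABA2 was not called without control replicate 5 (adjusted p = 0.0513) or salt replicate 4 (0.0569).

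Dehydration for 5 h on damp filter paper raised SEN1 10.3-fold (3.37 ± 0.22, n = 6), the sulphur-deficiency gene ATSDI1 6.32-fold (2.66 ± 0.30), FMO GS-OX4 3.53-fold (1.82 ± 0.18) and the NAC factor gene RD26 2.74-fold (1.45 ± 0.17) over control. The chaperone gene HSP90.2 fell 2.94-fold (-1.56 ± 0.14) and the arabinogalactan protein gene AGP2 fell 2.90-fold (-1.54 ± 0.17). Of the 22 ABA and dehydration response genes 7 rose (8 adjusted over the list alone) and none fell, with a median of 0.35 (adjusted p = 0.00144). RD20 (1.18 ± 0.22), TSPO (0.99 ± 0.22) and HAI1 (0.94 ± 0.19) were among them, and RD29A stood at -0.08 ± 0.24. Of 21 ABA receptors, phosphatases and kinases, 2 rose (3 adjusted over the list alone) and 6 fell, and the receptor genes PYL4 (-0.99 ± 0.15), PYL6 (-0.88 ± 0.21), PYL5 (-0.88 ± 0.17) and PYR1 (-0.86 ± 0.17) were among those that fell. That list had a median of 0.18 and a mean of -0.12 and was not called (adjusted p = 0.728). P5CS1 (1.14 ± 0.21), GOLS1 (1.00 ± 0.23) and BAM1 (0.65 ± 0.18) rose, also adjusted over the list alone, and their list of 5 was called (adjusted p = 0.0381). That call ended without background correction (adjusted p = 0.129), without chips of low correlation (0.135), with chips kept separate (0.0638) and within the 9-column files (0.0544). Of 8 cold-response genes 4 rose, also adjusted over the list alone, and the call (adjusted p = 0.0410) was lost at adjusted p = 0.278 with an estimated correlation, 0.110 with median scaling, 0.0610 without background correction, 0.0535 with background from the blank spots and 0.0638 with chips kept separate. Of the 4 usual reference genes 2 fell (3 adjusted over the list alone), and the list was called with median scaling only (adjusted p = 0.0936, and 0.0213 with median scaling). In all, 225 genes changed, 91 up and 134 down. Within the chips whose files have 9 columns the count was 80, and PYL4 (adjusted p = 0.0619), PYL5 (0.149) and GOLS1 (0.112) were not called. Of the 19 dehydration chips, 5 had a Spearman correlation under 0.8 with the rest of their group. Replicate 1 had 28.5% of genes above the blank spots and a Pearson correlation of 0.836 with the other replicates. Without chips of low correlation BAM1 was not called (adjusted p = 0.446).

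High light changed 52 genes against control, 24 up and 28 down. The early light-induced genes ELIP1 and ELIP2, whose proteins sit in the thylakoid, rose 3.22-fold (1.69 ± 0.15, n = 6) and 2.94-fold (1.56 ± 0.15). AT2G29500 rose 3.65-fold (1.87 ± 0.20) and HSP70 2.87-fold (1.52 ± 0.18), both in 6 of 6 replicates. All 3 flavonoid and anthocyanin genes rose, also adjusted over the list alone: MYB12 (0.86 ± 0.24), DFR (0.74 ± 0.20) and UF3GT (0.59 ± 0.19), and the list was called (adjusted p = 0.00357). AT5G05250 (-1.82 ± 0.20), ATSDI1 (-1.56 ± 0.30) and DIN11 (-1.30 ± 0.35) fell most. Of 7 heat shock proteins and factors 3 rose (4 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.000120). Of 6 reactive oxygen genes 2 rose, ELIP1 and ELIP2, also adjusted over the list alone, and the list was called (adjusted p = 7.64e-05). The called members are the early light-induced genes already named, so the call does not show that scavenging genes rose as a set. None of the 22 ABA and dehydration response genes rose, and 1, ERD14, fell (-0.67 ± 0.19), also adjusted over the list alone. With median scaling 26 genes rose and 16 fell, and without background correction 23 and 42. The count was 91 with chips kept separate, 162 when the spread came from these groups alone, 88 without the chips labelled ABA and ABA control, 24 within 9-column files, and 31 without replicate 5 or without replicate 6 of high light. The call of UF3GT ended without any single replicate of high light, and without control replicate 2, 3, 4, 5 or 6 (adjusted p from 0.0514 to 0.129), that of DFR without control replicate 1 (0.0621), that of MYB12 without high light replicate 3 (0.0514) or 6 (0.0692), that of DIN11 without replicate 4 (0.0567) or 6 (0.0706), and that of ERD14 without replicate 5 (0.0606) or 6 (0.0728), with median scaling (0.131) and with a block for file format (0.0639). UF3GT was also not called without background correction (0.0676) or without the filter on dim genes (0.0548). Within the 9-column files UF3GT (0.122), ERD14 (0.0817) and MYB12 (0.0887) were not called.

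**Figure D1:**
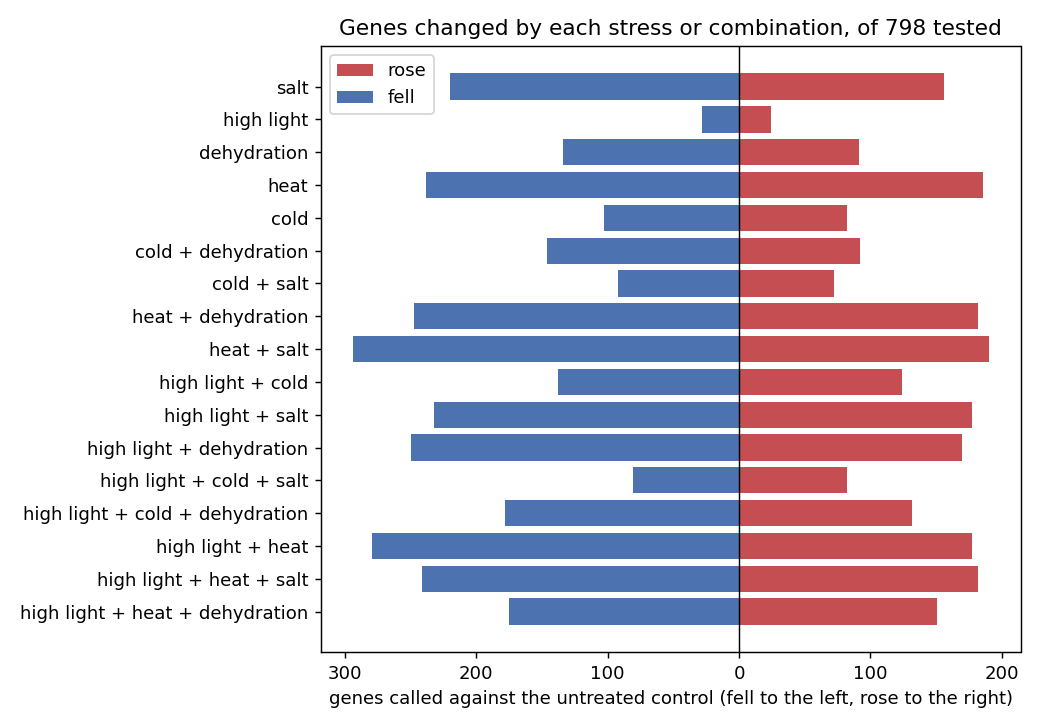
Number of genes called against untreated control in each of the 17 single or combined stresses, with genes that rose to the right and genes that fell to the left. High light alone had 52 calls and heat + salt had 484.

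Each stress was also averaged over all backgrounds of the factorial, which asks for its mean effect there, and this can differ from the effect of the stress alone. Heat changed 567 genes, with 244 up and 323 down, and HSP101 rose by 5.13 ± 0.07 and AT2G29500 by 4.69 ± 0.08, while COR15A fell by 2.58 ± 0.12. With median scaling, heat gave 325 up and 262 down, and the median of all genes moved from -0.07 to 0.06. Cold changed 408 genes, 207 up and 201 down (268 and 181 with median scaling, 182 and 200 without background correction), with AT3G60930 at 3.00 ± 0.06 and LBD41 at 2.27 ± 0.12 highest among genes bright in all groups, and RD20 at -2.45 ± 0.09 lowest. Salt changed 405 genes, 151 up and 254 down, dehydration 335, with 140 up and 195 down, and high light 307, with 157 up and 150 down (194 and 126 with median scaling). Averaged over backgrounds, 20 of the 22 ABA and dehydration response genes rose with salt and none fell, and 18 rose with dehydration and none fell, each also adjusted over the list alone (adjusted p = 2.32e-16 and 4.27e-12). On this average the same list was lower in the cold, with a mean of -0.60, 4 up and 14 down (adjusted p = 0.000463). Its lower value with heat, a mean of -0.54, 3 up and 15 down, was called with adjusted p = 0.0232 but adjusted p = 0.117 with an estimated correlation. RD26 (1.13 ± 0.07) and MAPKKK18 (1.16 ± 0.10) rose with dehydration, and PYL4 fell with both water stresses (-0.94 ± 0.06 with salt and -0.90 ± 0.06 with dehydration). NAC032 (0.89 ± 0.07), ELIP1 and ELIP2 (both 0.83 ± 0.05) rose most with high light, and LCR67 fell (-1.37 ± 0.23). Of 7 heat shock proteins and factors, 6 rose and none fell with heat (adjusted p = 1.71e-09), and 5 rose and 1 fell with high light (adjusted p = 0.000267), both also adjusted over the list alone. The cold-response list was called for salt, with 8 of 8 up (adjusted p = 5.15e-06), and for dehydration, with 7 of 8 up (adjusted p = 0.000672, adjusted p = 0.0681 with an estimated correlation). Other calls were for flavonoid genes, 3 of 3 down in the cold (adjusted p = 0.0280) and 3 of 3 up in high light (adjusted p = 0.0125), and for proline, galactinol and starch genes, 3 of 5 up with salt (adjusted p = 0.00217) and 4 of 5 down in the cold (adjusted p = 0.0389), each also adjusted over the list alone. Against control alone, by contrast, the ABA and dehydration response list had a mean of 0.25 in cold and 0.19 in heat and the proline list 0.37 in cold, none of them called, so the average and the single stress differ in sign. With chips kept separate the calls of the flavonoid and proline lists in the cold were lost, at adjusted p = 0.0781 and 0.0638. The call of the proline list was also lost without background correction (0.0544) and without chips of low correlation (0.0617). The reactive oxygen list, which holds ELIP1 and ELIP2, rose with high light, 3 of 6 up and 1 down (adjusted p = 0.0173, adjusted p = 0.0529 with an estimated correlation). The ABA and dehydration response list, 10 of 22 up and 4 down with high light (11 and 4 adjusted over the list alone), was not called (adjusted p = 0.0777), but was with median scaling (0.0357), without background correction (0.0119) and without the filter on dim genes (0.0402). The proline list, 3 of 5 up with dehydration, also adjusted over the list alone, was not called (adjusted p = 0.0558), but was with median scaling (0.0430) and without that filter (0.0402).

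Seedlings under combined stresses were compared with control to ask how the response to a mixture looks. In every combination with heat, HSP101 and AT2G29500 rose, HSP101 by between 4.99 ± 0.17 in heat + salt and 5.77 ± 0.17 in high light + heat (n = 6 in both). Heat + salt changed 484 genes (190 up, 294 down), with PYR1 (-2.01 ± 0.17) among those that fell, and heat + dehydration changed 429 (182 up, 247 down), with AT1G03070 at 4.79 ± 0.22 (n = 5). High light + heat changed 456 (177 up, 279 down), with GOLS1 at 4.78 ± 0.23 and ENODL2 at -2.85 ± 0.20. The triple stress with salt changed 423 (182 up, 241 down, 209 and 200 with median scaling, n = 4), with DREB2A at 4.28 ± 0.18 and GOLS2 at 4.11 ± 0.24, and the triple stress with dehydration changed 326 (151 up, 175 down, 187 and 148 with median scaling), with COR15A at -2.90 ± 0.29. In the cold combinations PUB19 rose at least 5.32-fold and AT3G60930 and AT1G74450 rose in each. Cold + salt changed 164 genes (72 up, 92 down), with LBD41 at 3.43 ± 0.29, and cold + dehydration 238 (92 up, 146 down), with JAZ5 at least 3.89-fold up. High light + cold changed 262 (124 up, 138 down), with AT1G78070 at 2.90 ± 0.18, high light + cold + salt 163 (82 up, 81 down) and high light + cold + dehydration 310 (132 up, 178 down), with RD29A at 2.95 ± 0.24. All 20 chips of high light + cold have 8-column files, and a block for file format gave 194 genes there (103 up, 91 down). High light + salt changed 409 genes (177 up, 232 down), with RD20 at 4.60 ± 0.22, and high light + dehydration 420 (170 up, 250 down), with TSPO at 5.63 ± 0.22, MAPKKK18 at 4.33 ± 0.25 and PYL4 at -3.44 ± 0.15. When the spread came from the groups compared alone, cold + dehydration gave 369 genes, cold + salt 329, high light + cold 441 and high light + cold + salt 291, and high light + salt gave 271 within the 9-column files. Median scaling changed the split to 95 up and 94 down for cold + dehydration, 75 and 73 for cold + salt, 215 and 240 for heat + salt, 91 and 73 for high light + cold + salt, 227 and 189 for heat + dehydration, 150 and 84 for high light + cold, and 215 and 209 for high light + heat. It moved the median of all genes from -0.09 to 0.06 in heat + dehydration, from -0.13 to -0.01 in high light + heat and from -0.15 to -0.02 in high light + heat + salt, and no background correction moved it from -0.16 to -0.04 in heat + salt, from -0.17 to -0.05 in high light + dehydration and from -0.15 to -0.04 in high light + heat + salt.

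Whether the effect of a pair equals the sum of its parts was tested as an interaction of 2 stresses. With cold and salt together RD20 lay 4.96 ± 0.30 below the sum, LEA4-5 at -4.02 ± 0.29, AT1G16850 at -3.80 ± 0.28, while PYL4 lay above it by 4.18 ± 0.21 and PYL5 by 2.26 ± 0.24. Of 22 ABA and dehydration response genes 17 lay below the sum and none above (1 above adjusted over the list alone), with a median of -1.58 (adjusted p = 7.56e-11). All 8 cold-response genes (median -1.88, adjusted p = 4.77e-07) and all 5 proline, galactinol and starch genes (median -1.67, adjusted p = 0.000427) lay below it, also adjusted over the list alone. The 4 usual reference genes lay above it, also adjusted over the list alone, without a call of the list (mean 0.72, adjusted p = 0.0568). That list was called without background correction (adjusted p = 0.0368), with background from the blank spots (0.0453), without the filter on dim genes (0.0403), without chips of low correlation (0.0315), with chips kept separate (0.0408) and without the chips labelled ABA and ABA control (0.0439). In all, 298 genes differed from the sum, 159 above and 139 below. Heat with salt gave 297, 144 above and 153 below, with LEA7 at -3.16 ± 0.25, LEA4-5 at -3.15 ± 0.29 and RD29B at -2.43 ± 0.31, and PYL4 at 2.34 ± 0.21. There the ABA and dehydration response list had 12 of 22 below and 1 above, also adjusted over the list alone (adjusted p = 0.000339), and 4 of 5 proline, galactinol and starch genes lay below (5 adjusted over the list alone, adjusted p = 0.00484).

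With high light and dehydration together TSPO lay 4.93 ± 0.30 above the sum, RD20 4.00 ± 0.30, RD29B 3.56 ± 0.31 and LEA7 3.50 ± 0.25, and PYL4 lay below it at -2.34 ± 0.21. Of the 22 ABA and dehydration response genes 18 lay above and none below, also adjusted over the list alone, with a median of 1.70 (adjusted p = 1.77e-18). The cold-response list (6 of 8 above, adjusted p = 1.02e-05) and the proline, galactinol and starch list (3 of 5 above, adjusted p = 0.0280) were called as well, with the same counts adjusted over the list alone. The cold-response list shares 3 of its 8 genes, ERD10, RD29A and LEA14, with the ABA and dehydration response list, so calls of both are not independent. In all, 223 genes differed from the sum, 105 above and 118 below, against 141 and 91 with median scaling and 88 genes within the 9-column files. High light with salt gave 67 genes (33 above, 34 below, and 42 and 34 with median scaling), among them LEA7 at -1.51 ± 0.25 and PYL4 at 1.14 ± 0.21. The ABA and dehydration response list had 1 of 22 below there, also adjusted over the list alone, and was not called (adjusted p = 0.128, but 0.00654 without background correction). That count was 112 without chips of low correlation, 117 with chips kept separate or without the chips labelled ABA and ABA control, 113 when the spread came from these groups alone, 101 without replicate 1 of salt, and 28 within the 9-column files.

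Among the other 4 pairs, high light with heat gave 156 genes (74 above, 82 below), with NAC102 at 2.22 ± 0.20 and HSFA7B at 2.21 ± 0.25 above the sum and AT1G21945 at -2.48 ± 0.27 and AT2G29500 at -2.01 ± 0.28 below, and the count was 244 when the spread came from these groups alone. High light with cold gave 18 (9 above, 9 below), with ELIP2 at -1.61 ± 0.21, ELIP1 at -1.47 ± 0.21 and AT2G29500 at -1.73 ± 0.28 below the sum and RD29A at 1.35 ± 0.34 above. It was 33 without background correction, 20 above and 13 below, 37 without chips of low correlation, 40 with chips kept separate, 41 without the chips labelled ABA and ABA control, and 90 when the spread came from these groups alone. There 2 of 6 reactive oxygen genes, ELIP1 and ELIP2 (3 adjusted over the list alone), and 2 of 7 heat shock genes (3 adjusted over the list alone) lay below the sum, with adjusted p = 1.29e-05 and 0.000463. The ABA and dehydration response and cold-response lists lay above it, with 2 of 22 and 1 of 8 genes called (3 and 2 adjusted over the list alone; adjusted p = 0.0486 and 0.00642), but adjusted p = 0.179 and 0.150 with an estimated correlation. The former call also ended without background correction (adjusted p = 0.0995) and in 5 other settings, the closest to the threshold at 0.0512. Cold with dehydration gave 114 genes (65 above, 49 below), with SEN1 at -3.84 ± 0.31, ATSDI1 at -2.95 ± 0.42 and HSP90.2 at 1.33 ± 0.20, and 42 within the 9-column files. There 2 of 5 proline, galactinol and starch genes lay below the sum (3 adjusted over the list alone), and the list was not called (adjusted p = 0.0581) but was in 4 other settings (0.0387 to 0.0482). Heat with dehydration gave 112 (72 above, 40 below, and 108 and 33 with median scaling), with SEN1 at -2.37 ± 0.32, BCB at 2.00 ± 0.29 and HSP90.2 at 1.93 ± 0.20. That count was 176 without chips of low correlation, 181 with chips kept separate and 17 within the 9-column files. Of 3 flavonoid genes 1 lay below the sum (2 adjusted over the list alone), and the list was not called (adjusted p = 0.0936) but was with median scaling (0.0417) and within the 9-column files (0.0379). A term for light, temperature and water together was called for 422 genes by a joint F test over 4 terms, among them PUB19, LEA7 and PYL4 (adjusted p = 5.51e-28, 5.95e-26 and 2.53e-25), which were chosen after their values were seen.

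**Figure D2:**
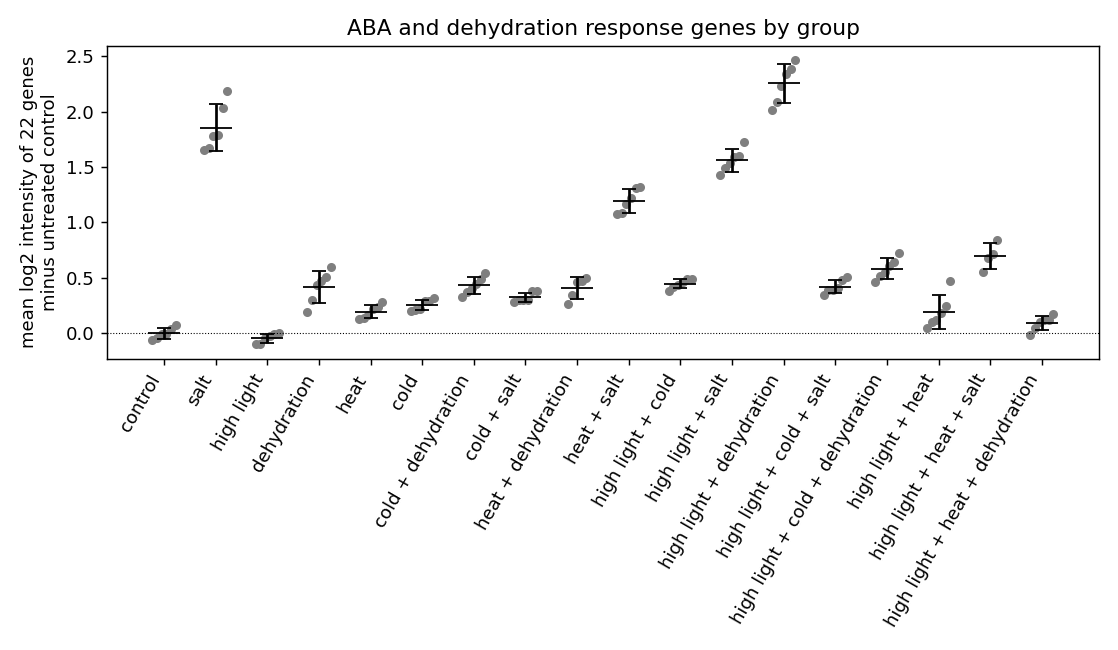
Mean log2 intensity of 22 ABA and dehydration response genes minus that in untreated control, for each of the 18 groups of the factorial. Points are biological replicates, bars the group mean ± SD. The mean was 1.85 in salt, 2.26 in high light + dehydration and 0.32 in cold + salt.

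**Figure D3:**
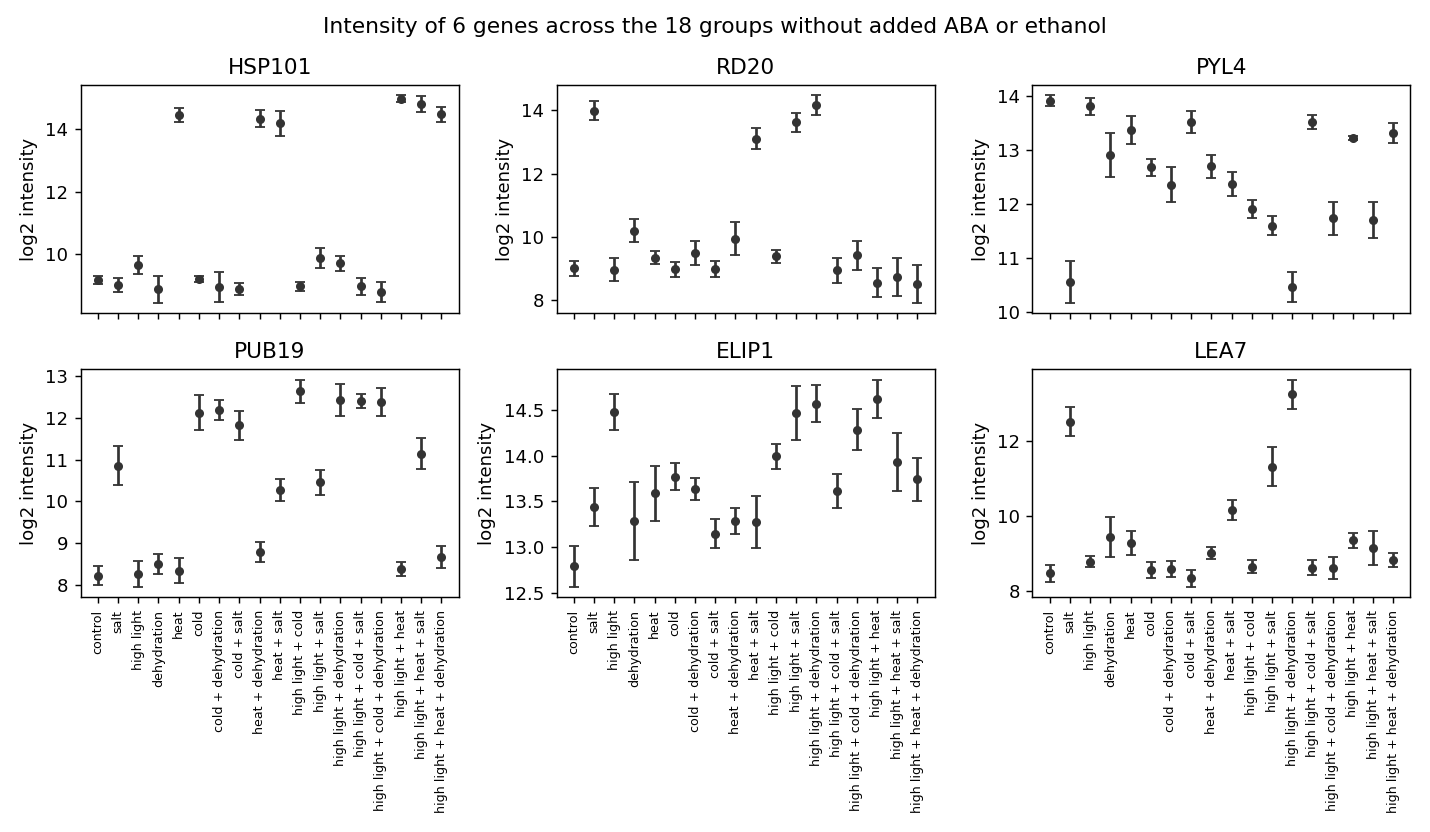
Log2 intensity of HSP101, RD20, PYL4, PUB19, ELIP1 and LEA7 in the 18 groups of the factorial, as mean ± SD over 4 to 6 biological replicates. Vertical axes differ between panels and do not start at 0. HSP101 stands at 14.4 in heat and 9.19 in control.

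Chips labelled ABA were compared with chips labelled ABA control, the ethanol solvent alone, to find the genes the hormone changes. The receptor gene PYL4 was at least 11.9-fold higher on the chips labelled ABA, the glutathione transferase gene GSTU5 at least 9.82-fold and PIP2;2 22.7-fold (4.50 ± 0.19, n = 5), while PYL13 was 16.6-fold lower (-4.06 ± 0.25). In the authors' table PYL4, GSTU5 and PIP2;2 lay the other way, at -4.83, -0.0642 and -1.21. Of 570 genes called here that the table also holds, 285 had the same sign there, and the correlation over 782 genes was -0.124. Of the 22 ABA and dehydration response genes 6 were higher and 10 lower (6 and 9 adjusted over the list alone), with a median of 0.06, a mean of -0.07 and no call (adjusted p = 0.649). Reactive oxygen genes were higher in 4 of 6, also adjusted over the list alone (adjusted p = 0.0428, adjusted p = 0.115 with an estimated correlation, and 0.0786 without chips of low correlation). The median share of genes above the blank spots was 73.4% on chips labelled ABA and 32.6% on chips labelled ABA control. The 10 used chips labelled ABA control had a median Spearman correlation of 0.347 with the ABA control column of the authors' table, against medians of 0.917 to 0.967 for the groups of the factorial with their own columns. Of the 10, 0 matched that column best and 7 had a correlation under 0.8 with the rest of their group. The 6 chips with this label that were left out, because the same scan stood under 2 labels, all matched that column best, with correlations from 0.440 to 0.943. The counts that follow rest on these chips. In all, 583 genes differed, 297 up and 286 down, and 607 differed between chips labelled ABA control and control (302 up, 305 down), where 4 of 6 reactive oxygen genes were lower (adjusted p = 0.0465, adjusted p = 0.117 with an estimated correlation, and 0.0896 without chips of low correlation). The usual reference genes were called in neither comparison (adjusted p = 0.202 and 0.171), with 2 of 4 higher and 1 lower in the former and 3 of 4 lower in the latter, also adjusted over the list alone, but in both with median scaling (0.0417 and 0.0333). Median scaling changed the splits to 337 up and 236 down in the former comparison and 256 and 346 in the latter, and no background correction to 267 and 311 and to 335 and 267. Median scaling moved the median of all genes from 0.02 to 0.18 in the former comparison and from 0.00 to -0.17 in the latter. Chips labelled ABA differed from untreated control in 6 genes, 5 up and 1 down, and none of the 22 list genes were among them (median -0.01). In the authors' deposited value table the ABA column exceeded the ABA control column by a median of 3.23 over the same 22 genes. Across 798 genes, which are not independent replicates, the change on chips labelled ABA against ABA control correlated with that of dehydration at r = -0.370 (Spearman -0.448; -0.0352 within the 9-column files) and with that of salt at r = -0.365 (Spearman -0.465). Between columns of the authors' table these were 0.562 (Spearman 0.470) and 0.721 (Spearman 0.557) over 782 genes, so the sign depends on which of the 2 sources is read.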

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

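The tests of technical explanations, the regroupings of samples and the file-format comparison below were chosen only after the results were seen. Replicates far from the others were sought in 200 combinations of a group and a measure, several measures sharing each of the 20 groups; 17 combinations had one, and chance gives about 1 in 20.

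The values are means of a list's log2 intensity minus the control mean, except where named. For ABA receptors, phosphatases and kinases, control replicate 2 stood at 0.0595 and high light + dehydration replicate 1 at -0.391. For circadian clock genes, heat + dehydration replicate 1 stood at 0.766, heat + salt replicate 5 at 0.564, high light + salt replicate 6 at 0.359 and high light + cold + dehydration replicate 2 at 1.28. For cold-response genes, high light + cold + salt replicate 1 stood at 0.229, high light + heat replicate 6 at 1.15 and ABA control replicate 4 at -0.987. Flavonoid genes stood at -0.141 in heat replicate 1. Proline, galactinol and starch genes stood at -0.266 in control replicate 6 and at 2.17 in high light + heat replicate 6. Reactive oxygen genes stood at -0.628 in cold + dehydration replicate 2. Usual reference genes stood at 0.0454 in control replicate 5, -0.870 in dehydration replicate 1 and -0.399 in high light + cold + dehydration replicate 5. The share of genes above the blank spots was 73.8% in high light + heat + dehydration replicate 2, against 65.1% to 68.4% in the others.

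Effects that differed between backgrounds by their interaction were counted as genes off the sum: 112 for heat + dehydration, 297 for heat + salt, 114 for cold + dehydration, 298 for cold + salt, 18 for high light + cold, 156 for high light + heat, 67 for high light + salt and 223 for high light + dehydration, and 422 genes had a term of light, temperature and water together. List means off the sum were, for ABA and dehydration response genes, -0.852 in heat + salt, -1.79 in cold + salt, 0.238 in high light + cold and 1.88 in high light + dehydration. Cold-response genes were at -2.09 in cold + salt, 0.522 in high light + cold and 1.57 in high light + dehydration, and proline, galactinol and starch genes at -1.32 in heat + salt, -1.90 in cold + salt and 1.06 in high light + dehydration. In high light + cold, heat shock genes were at -0.570 and reactive oxygen genes, of which ELIP1 and ELIP2 were called, at -0.610. In the authors' table, a column set that the comparisons do not use, ABA exceeded ABA control by a list median of 3.23.

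The chips labelled ABA showed no rise of the ABA and dehydration response genes against control. Dim hybridisation is argued against, since the median share of genes above the blank spots was 73.4% on these chips and 69.4% on control chips. The list median of 3.23 in the authors' table cannot tell whether the seedlings on these chips responded, since no such chip matched its ABA column best. Of the 14 used chips labelled ABA, 0 correlated best with the table's ABA column. Their median Spearman correlation was 0.744 with that column and 0.943 with the ABA control column. Chip files that hold other RNA than their label says therefore stay open as a candidate explanation. The genes that differed between chips labelled ABA and ABA control are thus not read as a response to the hormone. No biological explanation was tested beyond the absence of a response.

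The ABA and dehydration response list exceeded the sum under high light and dehydration by 1.88. Poor chips of the dehydration group are argued against, since the value was 1.85 without them. The file format is argued against more weakly, at 1.76 within the 9-column files. Those files hold only 2 replicates of dehydration and 4 of high light. High light did not raise the list's response to salt, where the interaction was -0.247 and the list stood at 1.56 in high light + salt. Salt alone already raised the list by 1.85, near the 2.26 of high light + dehydration, against 0.42 in dehydration alone. The salt values argue against a rise with any water stress only if that level left room for more, which was not tested. In the authors' table the list median was 1.75 for salt and 3.23 for ABA against ABA control, so higher levels occurred there. A biological interaction of light with dehydration may remain as a hypothesis, found and tested on the same data.

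The salt response of the same list was missing in the cold. Normalization between chips is argued against, since median scaling gave -1.68. Whether salt acted on the seedlings of the cold salt groups cannot be told: the changes at both light levels correlated at 0.531 across genes (0.535 with a block for file format, which differs between these groups, and 0.406 with the lower light level within 9-column files), but at -0.131 and -0.418 with salt against control, so the shared change need not be salt. Chips of cold + salt that were too dim to show a rise may explain part of it. There 61.8% of genes lay above the blank spots, against 66.1% in heat + salt. A dimmer group, high light + heat at 57.8%, still showed a rise of 1.76, but in the proline, galactinol and starch list. Dehydration chips, also at 57.8%, showed a rise of the ABA and dehydration response list itself, of 0.42. That is near the 0.32 of cold + salt, so it cannot tell whether a rise as large as in salt would show. On the cold + salt chips 72 genes rose against control, so they were not too dim for rises in general. In high light + cold + salt 70.7% lay above the blank spots, and the ABA and dehydration response list stood at 0.42, against 1.56 in high light + salt. Dimness is argued against for those chips. A biological effect of cold on the salt response stays open as a hypothesis.

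The samples were regrouped 100 times, the real grouping included. Regroupings address chance alone, not a batch or handling difference that goes with a group. In counts between 2 groups, chance is unlikely in each of the 19 comparisons, where 1 grouping, the real one, gave as many genes. The real count and the highest of the others were 376 and 263 for salt, 52 and 19 for high light, 225 and 135 for dehydration, 424 and 291 for heat, 185 and 102 for cold, 238 and 144 for cold + dehydration, 164 and 82 for cold + salt, 429 and 378 for heat + dehydration, and 484 and 340 for heat + salt. They were 262 and 174 for high light + cold, 409 and 287 for high light + salt, 420 and 305 for high light + dehydration, 163 and 71 for high light + cold + salt, 310 and 166 for high light + cold + dehydration, 456 and 331 for high light + heat, 423 and 297 for high light + heat + salt, 326 and 211 for high light + heat + dehydration, 583 and 498 for ABA against ABA control, and 607 and 562 for ABA control against control. Chance is also unlikely for average effects. There the real count and the highest other were 567 and 60 for heat, 408 and 6 for cold, and 405 and 66 for salt. They were 335 and 35 for dehydration, and 307 and 2 for high light.

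For genes off the sum, chance is unlikely for cold + salt (298, highest other 149), high light + cold (18 and 10) and high light + heat (156 and 64). The same holds for high light + salt (67 and 46), high light + dehydration (223 and 150) and the 422 genes with a joint term (highest other 35). For heat + salt (297 and 358) and cold + dehydration (114 and 126) 2 groupings, the real one included, gave as many. Chance is not excluded there, since a regrouping called more genes than the real one. For heat + dehydration (112 and 331) 10 groupings gave as many, so chance stays open. Regroupings that call many genes point to a structure of the samples, the single stresses. With the sum of the single stresses removed, 1 grouping gave as many for each of the 8 pairs, so chance is unlikely in that test. The highest others were 1 for heat + dehydration, 37 for heat + salt, 4 for cold + dehydration and 66 for cold + salt. They were 1 for high light + cold, 9 for high light + heat, 1 for high light + salt and 26 for high light + dehydration. For the 40 list calls with the preset correlation, 3 groupings gave as many (highest other 44, median of the others 17). For the 30 with an estimated correlation 1 did (highest other 1, median of the others 0). Chance is unlikely for the number of calls in both. It is not excluded for single calls that rest on the preset correlation alone, since regroupings often gave many of those.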

How the results depend on the processing

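Chosen only after the results were seen were the tests within 9-column files, without the chips labelled ABA and ABA control, with all chips as labelled, with ABA replicates numbered by the title line, with the authors' table for the correlations, and without single replicates outside the comparison of heat + dehydration or high light + heat + salt with control and the sum for heat + dehydration; the others were planned. A count was taken as moved when it changed by more than 1.5-fold. A correlation was taken as moved when it changed by at least the SD of its values without single replicates. By these rules the counts and correlations moved in none of 36 results with the replicate block or with the median over probes. The cause was not tested for any value below, except that 9-column files and omitted chips leave fewer samples. The correlation across genes of the change on chips labelled ABA with dehydration was -0.479 with median scaling, -0.327 without background correction, -0.384 without the filter on dim genes, -0.290 with a block for file format, -0.329 without chips of low correlation, -0.387 with chips kept separate and -0.0352 within 9-column files. That with salt was -0.368 with median scaling, -0.340 without background correction, -0.344 without the filter on dim genes, -0.337 without chips of low correlation, -0.353 with background from the blank spots and -0.374 with all chips as labelled. In the authors' table both reversed, to 0.562 and 0.721. High light against control gave 91 genes with chips kept separate, 162 with only the groups compared, 88 without the chips labelled ABA and ABA control and 24 within 9-column files. Genes off the sum for high light + cold were 33 without background correction, 37 without chips of low correlation, 40 with chips kept separate, 90 with only the groups compared and 41 without the chips labelled ABA and ABA control. For high light + salt they were 112 without chips of low correlation, 117 with chips kept separate and also without the chips labelled ABA and ABA control, 113 with only the groups compared and 28 within 9-column files. For heat + dehydration they were 176 without chips of low correlation, 181 with chips kept separate and 17 within 9-column files. With only the groups compared, cold gave 295 genes, cold + dehydration 369, cold + salt 329, high light + cold 441, high light + cold + salt 291, and high light + heat off the sum 244. Within 9-column files, dehydration gave 80, high light + salt 271, cold + dehydration off the sum 42 and high light + dehydration off the sum 88. Leaving out single replicates gave 31 to 69 genes for high light against control, 46 to 101 off the sum for high light + salt, and correlations from -0.384 to -0.347 with dehydration and from -0.368 to -0.356 with salt. In the authors' table, genes higher on chips labelled ABA than ABA control reversed: PYL4 was at -4.83, GSTU5 at -0.0642 and PIP2;2 at -1.21. There, 82 other values of named genes moved by more than the spread between replicates and kept their direction, and HSP101 was 6.62 in heat. Not run were 9-column files for comparisons with groups that had too few replicates of such chips, 0 in high light + cold and 1 in heat + salt. In heat + salt 17 of 20 chips have 8 columns. Both groups against control and against their sum, the averages and the joint term thus had no such check. Signal over background limits dim genes: 129 of 927 genes were not tested.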

Other observations

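The tests on salt in the cold and on resemblance between chips and the authors' columns were chosen only after the results were seen, as were the genes named here.

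Cold + salt differed from cold alone in 29 genes, 9 up and 20 down, and high light + cold + salt from high light + cold in 100 genes, 40 up and 60 down. Of these, 19 were called at both light levels, all 19 in the same direction, and 13 of the 19 moved opposite to a called change in salt against control. LBD41 rose by 1.52 ± 0.29 and 2.14 ± 0.29 at the lower and the higher light level, and the receptor gene PYL4 by 0.84 ± 0.15 and 1.60 ± 0.15 (n = 6 each). The calmodulin-like gene CML37 was at -1.50 ± 0.21 and -1.33 ± 0.21, ABF1 at -1.40 ± 0.17 and -1.46 ± 0.17, and COR15A at -0.95 ± 0.29 and -1.34 ± 0.29. Across 798 genes, which are not independent replicates, the changes at both light levels correlated at r = 0.531 (Spearman 0.418), while those with salt against control were -0.131 and -0.418. File format differs between these groups: all 20 chips of high light + cold and none of high light + cold + salt have 8 columns, against 2 of 25 for cold and 14 of 36 for cold + salt. With a block for format the counts were 31 and 64, 21 genes were called at both levels in the same direction, and r was 0.535. With the lower light level within 9-column files r was 0.406 (Spearman 0.270), and 58 genes were called at that level. Dehydration changed 19 genes against cold alone and 16 against high light + cold, but 225 against control and 430 against high light alone. File format differs here as well, since all 20 chips of high light + cold and 0 of high light + cold + dehydration have 8 columns.

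The chips of high light + dehydration had a median Spearman correlation of 0.921 with the ABA column of the authors' table, and of 0.775 with its control column, but of 0.966 with their own column, which 22 of 22 chips matched best. Chips labelled ABA had 0.744 with the ABA column and 0.943 with the ABA control column. Chips labelled ABA differed from untreated control in 6 genes: HSP70 (1.17 ± 0.19), AT1G32920 (0.96 ± 0.17), NAC102 (0.72 ± 0.15), AT5G61820 (0.83 ± 0.18) and ATAF1 (0.63 ± 0.15) were higher and AT1G14010 (-0.69 ± 0.16) was lower. In the authors' table, 248 of 782 genes lay at least 2-fold apart between the ABA and ABA control columns, and 7 between ABA control and control.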
